A study of Mus musculus with 6 samples.

How the data were processed

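The series holds 6 RNA sequencing libraries of mouse tumour-associated macrophages, 3 labelled wild type (WT) and 3 labelled HO1-KO. Per the labels' protocols, the macrophages were sorted by flow cytometry, polyadenylated RNA was extracted, libraries were made with the Ovation SoLo RNA-Seq kit and sequenced in pairs on a NovaSeq instrument. Other labels of the same samples name ATAC sequencing and peripheral blood. The protocol, the RNA molecule and the gene table were followed here.

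The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3, HTSeq 0.9.1, DESeq2 and the genome build mm10. Neither the annotation release nor the strand setting of the counting is given in the sources used here, so reads of a gene and of a gene that overlaps it cannot be told apart. The file holds 1 table of 52636 genes and 6 libraries, and 97 gene symbols occur more than once and were kept apart by their identifier. Although the file is named for counts, the deposited values are a normalized signal. Each library sums to between 20013276 and 20014640, and the low values skip whole numbers at regular steps, as whole reads scaled to a shared total and rounded up would. The sources used here do not state this scaling. A scale factor was found for each library, and between 99.82% and 99.91% of the values above 0 fell exactly on its steps. The factors gave 14438314, 12640222 and 14893952 reads for WT replicates 1 to 3 and 17144860, 13807889 and 12672362 for HO1-KO replicates 1 to 3. On 6 simulated libraries of 52636 genes, made with known depths in the same way, the search gave the depths without error. On these reads, chi-square per degree of freedom between replicates of a genotype lay between 2.59 and 14.5, so that no 2 libraries were alike within sampling noise.

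Because the values are not raw counts, the count model planned before the data were examined was replaced by limma 3.58.1 in R 4.3.3 on log2(CPM + 0.25), with a mean-variance trend and robust empirical Bayes. CPM were computed from the deposited values with an own implementation of trimmed mean of M values (TMM) factors, trimmed at 30% for ratios and 5% for levels, which lay between 0.961 and 1.05. Genes with a deposited value of at least 15, which is 0.75 CPM, in at least 3 libraries were tested, 17801 in all. The model held genotype only, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Standard errors and 95% intervals come from the same fit. Intervals cover the spread between libraries. In a single-gene exact permutation test, 3 libraries against 3 cannot give a p under 0.1, so none was used.

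For groups of genes, 30 lists fixed before the data were examined were used, for programmes of macrophages and for markers of other cell types and of RNA quality. The 28 lists with at least 5 tested members were tested with camera from limma, two-sided, with a preset correlation of 0.01 and adjustment over these lists. Camera with an estimated correlation and fry were run beside it. Of the list genes, 6 were not found under their symbol in the table. Genes are named by a rule fixed before the data were examined. It takes Hmox1. It takes the 10 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 3, every HO1-KO library on the same side of every WT library, and a symbol that is no gene model number or pseudogene. It adds up to 4 members of each list with the smallest p, and members of cell type or quality lists needed to describe a library that stands apart. Genes outside this rule are said to be chosen after their values were seen. Coordinates come from GENCODE release M21 for GRCm38, the assembly also called mm10, in which 17760 of the 17801 tested gene identifiers were found.

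The steps were tested on simulated libraries with the depths and means of these 6 libraries and 17814 genes tested. For the comparison of HO1-KO with WT, 71.4% of 98 genes changed 1.5-fold and 92.7% of 96 genes changed 2-fold were called in the right direction, and 5.36% of all calls were unchanged genes. A list of 20 raised genes was called and none of 29 lists of unchanged genes was. Simulated genes varied independently, whereas the estimated correlation within a real list reached 0.60 (ribosomal proteins). The simulation therefore does not show how often the preset-correlation test passes lists of genes that vary together. It also gave all genes the same spread between libraries (dispersion 0.00285) and changed few genes, as many up as down. Its rates need not hold for genes of low level or larger spread, or where many genes change.

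The alternatives planned before the data were examined were median-of-ratios and upper-quartile factors, no filter, a filter of 1 CPM, the replicate numbers as a block, each library left out, limma-voom on the reads given by the scale factors, non-robust empirical Bayes, and the other list tests. Added after seeing the data were pseudocounts of 0.1 and 1 CPM, the deposited scaling alone, and levels relative to the mean of 4 Y-linked genes in each library, the last also with each library left out for Hmox1 and the programme lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and the depths were computed with numpy 2.4.6 and pandas 2.3.3. All 6 libraries and all value columns were used.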

Results

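Gene expression was measured by RNA sequencing in tumour-associated macrophages of the mouse, the macrophages that infiltrate a tumour, isolated by flow cytometric sorting. The series compared 3 libraries labelled wild type (WT) with 3 libraries labelled knockout for heme oxygenase-1 (HO1-KO). Heme oxygenase-1 is the inducible enzyme that breaks heme down to biliverdin, carbon monoxide and iron, and it is encoded by Hmox1. The series title places the comparison in the immunosuppressive programme of these macrophages, and the question addressed was which genes and gene groups differed when the enzyme was deleted. The deposited table lists 52636 genes, of which 17801 passed the filter on low values and were tested. The steps between the deposited values corresponded to 12640222 to 14893952 assigned reads per WT library and 12672362 to 17144860 per HO1-KO library. The labels do not say whether the 3 libraries of a genotype came from separate mice, so p-values measure the spread between these libraries, which may be technical.

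Hmox1 (ENSMUSG00000005413; GRCm38/mm10 chromosome 8, 75093621 to 75100589, plus strand, protein-coding) was lower in every HO1-KO library than in every WT library. Its level was 289.8, 288.1 and 265.9 CPM in WT replicates 1, 2 and 3 and 121.9, 150.8 and 168.8 CPM in HO1-KO replicates 1, 2 and 3. The means were 281 ± 13.3 CPM (SD, n = 3) in WT and 147 ± 23.7 CPM (SD, n = 3) in HO1-KO, so that 52.3% of the WT level remained. The log2 fold change was -0.94 ± 0.09 (SE; 95% interval -1.13 to -0.76; limma, adjusted p = 5.9e-08). The table gives 1 value per gene, so reads from exons that a deletion leaves in place were not separated from the others. The Y-linked genes Eif2s3y, Kdm5d and Uty, which are expressed only from the Y chromosome, also were lower in HO1-KO, with log2 fold changes of -0.66 ± 0.08, -0.61 ± 0.09 and -0.60 ± 0.10 (SE). Ddx3y fell by 0.43 ± 0.08, and Xist, the transcript of the inactive X chromosome, stayed between 0.365 and 1.98 CPM in the 6 libraries. Relative to the mean of these 4 Y-linked genes in each library, a scaling chosen after seeing the data, the Hmox1 log2 fold change was -0.37 (95% interval -0.65 to -0.09; limma, adjusted p = 0.021). On this scale, log2 Hmox1 minus that mean, HO1-KO replicate 3 (1.903) lay above WT replicate 3 (1.839). The value lay between -0.51 and -0.18 when a library was left out, and it did not pass without WT replicate 1 or 2 or HO1-KO replicate 1 (limma, adjusted p = 0.0894, 0.0743 and 0.0891).

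**Figure D1:**
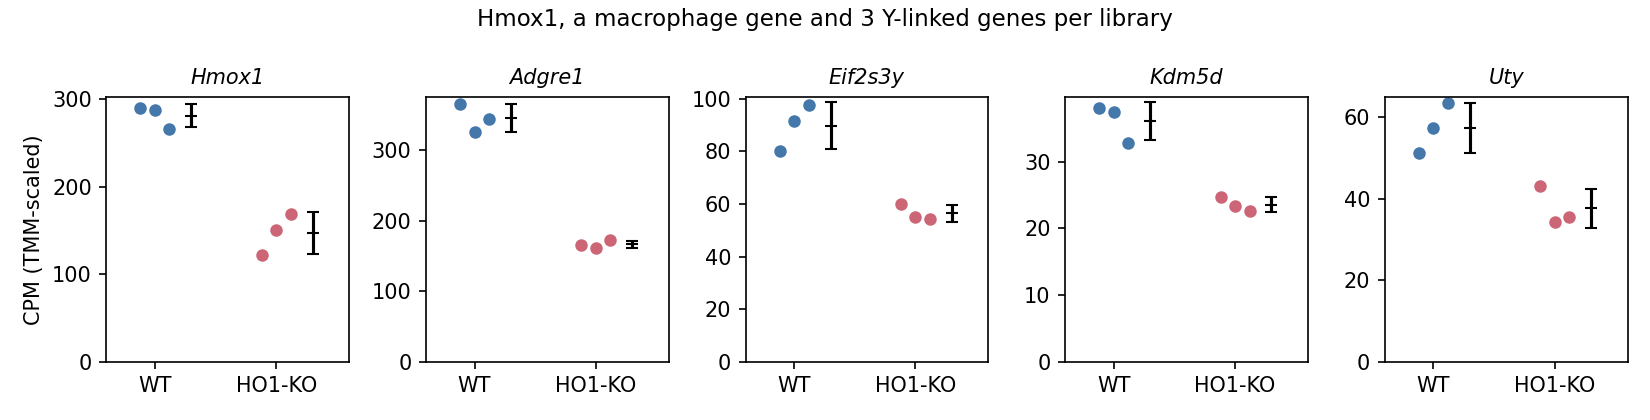
Level of Hmox1, of the macrophage gene Adgre1 and of the Y-linked genes Eif2s3y, Kdm5d and Uty in CPM (vertical axis, starting at 0) in the WT and HO1-KO libraries. Points are libraries and the bars beside them are the mean and SD of 3 libraries, and every HO1-KO library lies below every WT library for each of these genes, and Hmox1 falls from a mean of 281 to 147 CPM.

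Across the transcriptome, 9000 of the 17801 genes tested changed (limma, adjusted p under 0.05), with 4448 higher and 4552 lower in HO1-KO. This balance depends on the scaling, and the deposited scaling alone gave 5599 higher and 3742 lower. Of the 9000 genes called with the main scaling, 616 rose and 652 fell more than 2-fold. The first principal component carried 74.7% of the variance and separated the genotypes, and the 2 groups did not overlap for 56.5% of genes, against 10% expected by chance. Relative to the Y-linked genes, which moves the median of all genes from 0.01 to 0.59 (log2), the split was 12031 higher and 745 lower. Among genes with a mean log2 CPM of at least 3 that met the rule fixed beforehand, the largest rise was that of Hal, histidine ammonia-lyase, at 2.57 ± 0.407 CPM in WT and 110 ± 4.73 CPM in HO1-KO (SD, n = 3, log2 fold change 5.30 ± 0.11, SE). Others with large rises were Cr2 (1.84), Tnfrsf19 (1.70), Ighd (1.66), Iglc2 (1.63), Cd79a, Sema6a (1.56), Pllp (1.55) and Ms4a1 (1.54), on the log2 scale. Cr2, Ighd, Iglc2, Cd79a and Ms4a1 encode receptors and immunoglobulin chains of B cells. Under the same rule and limit the largest falls were those of Cd209b (-3.36), Ctsk (-2.85), Gzmb (-2.85), Ear2 (-2.81), Rnf150 (-2.70), Atp6v0d2 (-2.63), H2-M2 (-2.59), Slc9a4 (-2.40), Ms4a4b (-2.37) and Mfge8 (-2.25, all log2). Genes of lower level fell more, among them Cd8b1 (-4.46), Mcpt4 (-4.40) and Nkg7 (-4.26). Ctsk, the collagen-degrading cathepsin K, went from 388 ± 14.8 to 53.9 ± 5.43 CPM, and Atp6v0d2, a subunit of the vacuolar proton pump, from 335 ± 24.5 to 54.0 ± 6.81 CPM (SD, n = 3). Ear2, Iglc2 and H2-M2 belong to families of similar genes, whose reads can be split between members, so their values are less certain.

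Genes that mark macrophages fell together in HO1-KO. Of 23 tested members of the macrophage identity list, 22 fell and 1 did not pass, with 23 lower when adjusted over the list alone, and the median log2 fold change was -0.71 (camera adjusted p = 2.85e-13, adjusted p = 0.19 with an estimated correlation). Adgre1, which encodes the surface marker F4/80, fell from 345 ± 19.9 to 166 ± 5.60 CPM (SD, n = 3, -1.05 ± 0.07, log2, SE), C1qb, a chain of complement C1q, fell by 1.06 ± 0.08, and Cd68 fell by 0.96 ± 0.07. The lysosome and phagocytosis list fell in 30 of 31 members, and in the same number adjusted over the list alone (median -0.71, camera adjusted p = 3.33e-17, adjusted p = 0.162 with an estimated correlation). Its members included Axl, a receptor for apoptotic cells (-1.38 ± 0.08), and the protease gene Ctsd (-1.16 ± 0.08). It shares Cd68, Mertk, Fcgr1, C1qa, C1qb and C1qc with the macrophage list, so the falls of both lists are not independent. The Y-linked genes had a median of -0.61 beside these lists, and relative to them the medians of both lists were -0.13, with 8 lower and 2 higher members in the macrophage list and 11 lower and 3 higher in the lysosome list.

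Most genes of the immunosuppressive list were also lower. Of 34 tested members, 30 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone (median -0.62, camera adjusted p = 3.09e-11, adjusted p = 0.162 with an estimated correlation). Mmp12, macrophage elastase, fell from 1197 ± 43.9 to 397 ± 9.46 CPM (-1.59 ± 0.06), and Gpnmb, a glycoprotein of lipid-laden macrophages, from 400 ± 26.6 to 121 ± 8.73 CPM (-1.73 ± 0.07, SD with n = 3 and log2 SE). Chil3, a chitinase-like protein of alternatively activated macrophages, fell by 1.85 ± 0.09 and Clec7a, the beta-glucan receptor, fell by 1.15 ± 0.06. The gene that rose was the chemokine gene Ccl24 (1.23 ± 0.10), named after its value was seen. Among genes likewise chosen after their values were seen, Mrc1 and Cd274, which encode the mannose receptor and the checkpoint ligand PD-L1, both fell by 0.62 ± 0.06, and Arg1, which encodes arginase 1, fell by 0.35 ± 0.06. Relative to the Y-linked genes the list median was -0.04, with 11 lower and 4 higher members. In that setting Mrc1 and Cd274 were at -0.04 and Arg1 at 0.23, and none of the 3 passed.

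Interferon-responsive genes were lower as well. In the type I interferon list 29 of 32 members fell, 1 rose and 2 did not pass, also adjusted over the list alone (median -0.61, camera adjusted p = 3.09e-11, adjusted p = 0.0846 with an estimated correlation). Oasl2 fell by 0.91 ± 0.08 (log2, SE) and Ifih1 fell by 0.84 ± 0.08. The member that rose was Isg20 (0.29 ± 0.10; limma, adjusted p = 0.0255), named after its value was seen, and it did not pass without WT replicate 2 (adjusted p = 0.104), without HO1-KO replicate 1 (adjusted p = 0.132) or without HO1-KO replicate 2 (adjusted p = 0.0682). In the list of interferon-gamma response and antigen presentation, 25 of 27 members fell and 2 did not pass, also adjusted over the list alone (median -0.61, camera adjusted p = 7.2e-13, adjusted p = 0.162 with an estimated correlation). Ctss, the protease that trims the invariant chain, fell by 1.01 ± 0.06, the chemokine gene Cxcl9 fell by 1.05 ± 0.08 and the guanylate-binding protein gene Gbp3 fell by 0.96 ± 0.07. Of 32 members of the inflammatory list, 22 fell, 4 rose and 6 did not pass, with 23 lower and 4 higher when adjusted over the list alone (median -0.39, camera adjusted p = 1.99e-05, adjusted p = 0.234 with an estimated correlation). The falls included Il1a (-1.03 ± 0.07), Acod1, the enzyme that makes itaconate (-0.88 ± 0.07), and Ccl5 (-1.13 ± 0.09). Cxcl3 (0.53), Il12a (0.86), Ccr7 (0.82) and Cxcl2 (0.18) rose, all named after their values were seen, and Cxcl2 did not pass with the replicate numbers as a block (limma, adjusted p = 0.0782). It also did not pass without WT replicate 1 or 2 (limma, adjusted p = 0.155 and 0.0722) or without HO1-KO replicate 2 or 3 (limma, adjusted p = 0.0528 and 0.204). Most of these falls were no longer called relative to the Y-linked genes. In that setting the medians of the 2 interferon lists were both -0.03, with 4 lower and 3 higher members in the type I list and 8 lower and 3 higher in the interferon-gamma list. The inflammatory list turned to a median of 0.19, with 3 lower and 13 higher members. It passed as lower than the other genes (camera adjusted p = 0.00581), as did both interferon lists. This scaling shifts every gene by the same amount, so the distance of a list from the other genes does not change. Camera in this setting therefore does not test whether a list fell further than the Y-linked genes.

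Heme and iron genes mostly fell with the main scaling, but not relative to the Y-linked genes. Of 26 tested members, which include Hmox1, 19 fell, 1 rose and 6 did not pass, also adjusted over the list alone (median -0.48, turning to 0.09 relative to the Y-linked genes, camera adjusted p = 2.69e-05, adjusted p = 0.162 with an estimated correlation). Alas1, which catalyses the first step of heme synthesis, fell from 164 ± 4.56 to 70.9 ± 8.74 CPM (-1.22 ± 0.08), and Ncoa4, the cargo receptor for ferritin breakdown, fell by 0.83 ± 0.07. Tfrc, the transferrin receptor, rose from 359 ± 52.2 to 758 ± 73.6 CPM (1.08 ± 0.09, SD with n = 3 and log2 SE). In this list 6 members were lower and 9 higher relative to the Y-linked genes. It passed there as lower than the other genes (camera adjusted p = 4.56e-05), from which its distance is the same in both scalings. Among targets of the oxidative stress factor NRF2, 13 of 23 fell, 1 rose and 9 did not pass, also adjusted over the list alone (median -0.29, turning to 0.29 relative to the Y-linked genes, camera adjusted p = 0.00261, adjusted p = 0.344 with an estimated correlation). Relative to the Y-linked genes 1 member was lower and 12 were higher. The list did not pass there (camera adjusted p = 0.18), although its distance from the other genes was unchanged. The lost call therefore does not show that the list fell no further than the other genes. This list shares Hmox1, Ftl1 and Fth1 with the heme and iron list. Srxn1, Gstm1 and Cat had log2 fold changes of -0.74 ± 0.10, -0.73 ± 0.10 and -0.54 ± 0.07. They were at -0.17 ± 0.14, -0.15 ± 0.13 and 0.04 ± 0.10 (SE) relative to the Y-linked genes, and none of these calls remained (limma, adjusted p = 0.281, 0.331 and 0.741). The member that rose was Gclc (0.36 ± 0.08), named after its value was seen. Of 24 members of the lipid efflux list, 16 fell and 5 rose, also adjusted over the list alone (median -0.49, turning to 0.08 relative to the Y-linked genes, camera adjusted p = 0.000399, adjusted p = 0.318 with an estimated correlation). Lpl, lipoprotein lipase, fell from 867 ± 1.76 to 189 ± 16.0 CPM (SD, n = 3, -2.20 ± 0.07, log2, SE), Cd5l fell by 1.42 ± 0.09 and Lipa, lysosomal acid lipase, fell by 1.07 ± 0.06. Scd1 rose (1.37 ± 0.07). The others that rose, named after their values were seen, were Scd2 (0.57), Fasn (0.68) and Acaca (0.40), which act in fatty acid synthesis and desaturation, and Apoc1 (1.63), which was at 0.345 CPM in WT and 1.59 CPM in HO1-KO. In the lipid efflux list 5 members were lower and 9 higher relative to the Y-linked genes. The list passed there as lower than the other genes (camera adjusted p = 0.000187), with its distance from them again unchanged.

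Several groups rose, beside rises of genes of the T cell and B cell lists and falls of Y-linked genes in the same libraries. In the proliferation list 22 of 34 members rose, 1 fell and 11 did not pass, with 23 higher and 1 lower when adjusted over the list alone (median 0.40, camera adjusted p = 1.56e-06, adjusted p = 0.228 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 93.3 ± 1.82 to 157 ± 5.02 CPM (SD, n = 3, 0.74 ± 0.07, log2, SE), and Cdk1 and Mcm5 rose by 0.79 ± 0.09 and 0.71 ± 0.07. Mcm5 lies close to Hmox1 on chromosome 8 (75109569 to 75128439). The member that fell was Tk1 (-0.77 ± 0.11), named after its value was seen, whose call ended relative to the Y-linked genes (-0.19 ± 0.14, limma, adjusted p = 0.238). In the cholesterol synthesis list 15 of 22 members rose, 2 fell and 5 did not pass, also adjusted over the list alone (median 0.41, camera adjusted p = 0.000455, adjusted p = 0.303 with an estimated correlation). Cyp51 rose by 0.92 ± 0.08 and Sqle, squalene epoxidase, by 0.77 ± 0.07, and the members that fell included Mvd (-0.76), named after its value was seen. The call of Mvd ended relative to the Y-linked genes (-0.18 ± 0.16, SE, limma, adjusted p = 0.32). Of 30 genes of the ATF4 and endoplasmic reticulum stress list, 18 rose, 4 fell and 8 did not pass, also adjusted over the list alone (median 0.39, camera adjusted p = 4.13e-05, adjusted p = 0.211 with an estimated correlation). Asns, asparagine synthetase, rose from 181 ± 18.8 to 413 ± 34.7 CPM (SD, n = 3, 1.19 ± 0.08, log2, SE), and the serine synthesis genes Psat1 and Phgdh by 1.02 ± 0.07 and 1.03 ± 0.08. Ribosomal protein genes rose in 21 of 36 members, with 23 higher when adjusted over the list alone and a small median of 0.19 (camera adjusted p = 4.71e-05, adjusted p = 0.454 with an estimated correlation). Relative to the Y-linked genes the medians of these 4 lists were 0.97, 0.98, 0.96 and 0.77, with 33, 20, 29 and 36 members higher and 0 lower.

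**Figure D2:**
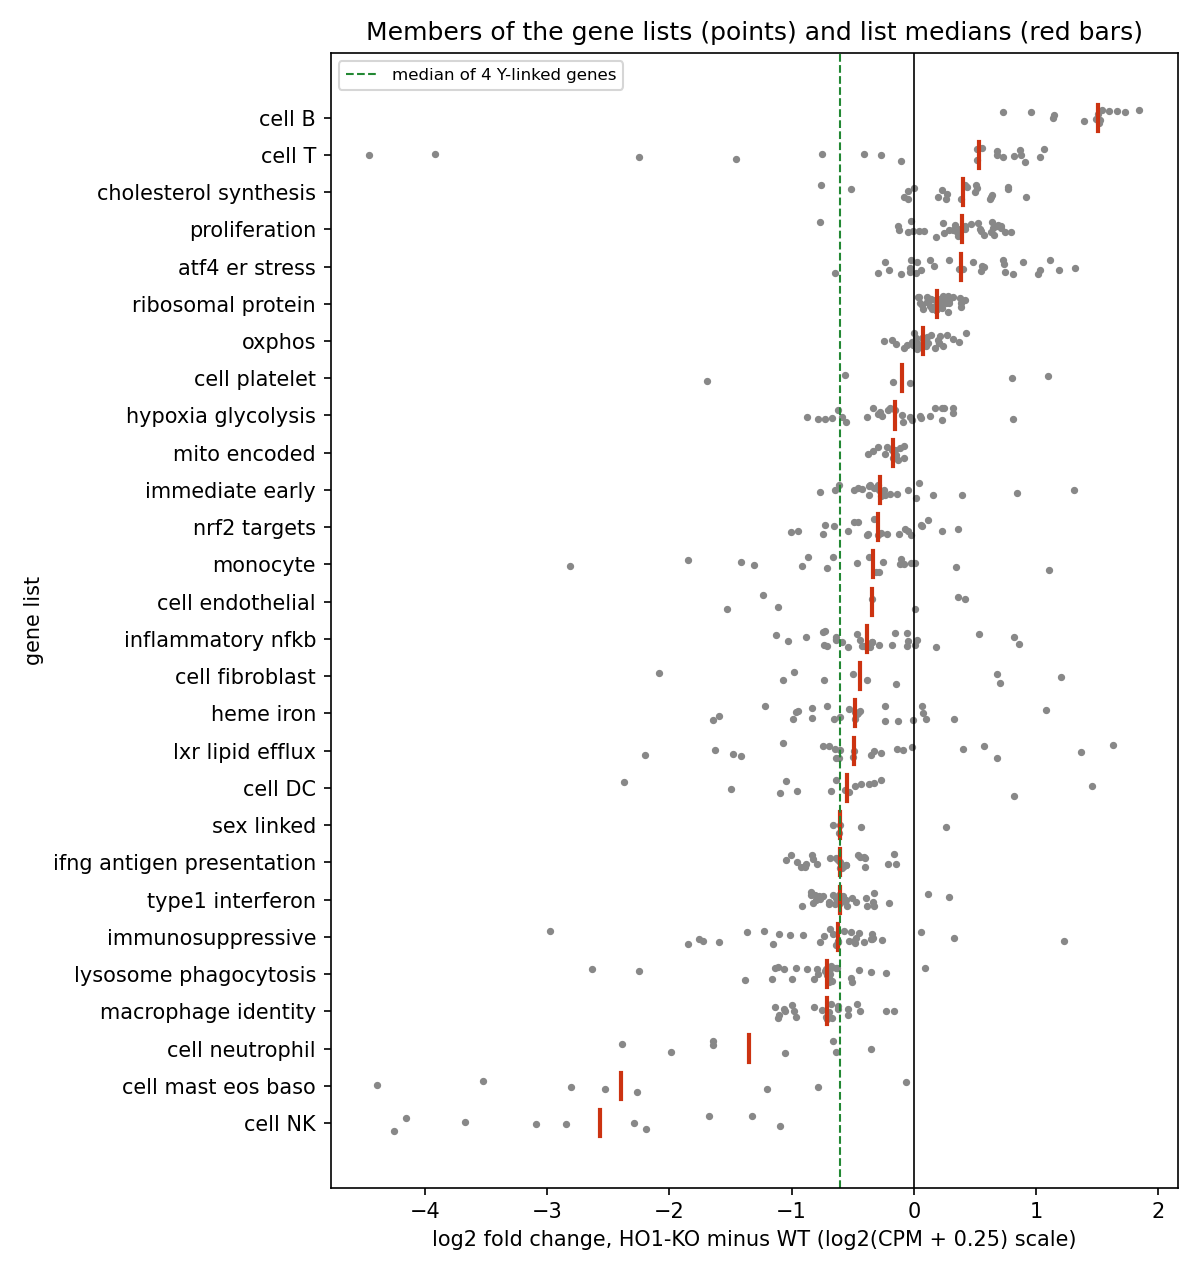
Log2 fold change of each tested member (points, HO1-KO minus WT, horizontal axis) in the gene lists with at least 5 tested members, ordered by list median (red bars, vertical axis lists). The dashed line marks the median of the 4 Y-linked genes at -0.61, close to the medians of the macrophage (-0.71), immunosuppressive (-0.62) and both interferon lists (-0.61).

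Markers of other cell types moved in different directions. All 14 members of the B cell list rose, also adjusted over the list alone (median 1.51, camera adjusted p = 2.65e-12, adjusted p = 0.0846 with an estimated correlation). Ms4a1, which encodes CD20, went from 19.9 ± 1.72 to 59.0 ± 8.57 CPM, and Igkc, the kappa constant chain, from 45.2 ± 3.40 to 119 ± 9.70 CPM (SD, n = 3). All 10 tested members of the natural killer (NK) cell list fell, also adjusted over the list alone (median -2.57, camera adjusted p = 1.5e-09, adjusted p = 0.0846 with an estimated correlation). Nkg7 went from 19.5 ± 0.267 to 0.813 ± 0.328 CPM and Prf1, perforin, from 20.7 ± 0.936 to 0.957 ± 0.329 CPM (SD, n = 3). In the T cell list 12 of 20 members rose, 7 fell and 1 did not pass, also adjusted over the list alone, with a median of 0.54 and a mean of -0.22 (camera, direction up, adjusted p = 0.0418, adjusted p = 0.454 with an estimated correlation). This list did not pass with the deposited scaling alone (median 0.62, camera adjusted p = 0.0785), relative to the Y-linked genes (median 1.11, 14 higher and 4 lower, camera adjusted p = 0.94) or with fry (adjusted p = 0.0541). In the first 2 of these settings the list median was higher, and so was the median of all genes (0.09 and 0.59, against 0.01). Both settings move the list and the other genes by about the same amount, so the distance between them hardly changed. Why the call ended there was not tested. Lat, a signalling adaptor of the T cell receptor, rose from 49.1 ± 2.84 to 103 ± 4.20 CPM and the transcription factor gene Tcf7 from 207 ± 12.98 to 425 ± 35.3 CPM (SD, n = 3). Cd8a fell from 13.6 ± 0.860 to 0.717 ± 0.410 CPM and Cd8b1 from 11.2 ± 0.703 to 0.292 ± 0.176 CPM (SD, n = 3). All 8 tested neutrophil genes fell, also adjusted over the list alone (median -1.35, camera adjusted p = 5.45e-05, adjusted p = 0.0846 with an estimated correlation). Their median was -0.77 relative to the Y-linked genes, with 5 of 8 lower. In the mast cell, eosinophil and basophil list 7 of 8 tested members fell, also adjusted over the list alone. Its median was -2.39 (camera adjusted p = 1.99e-05, adjusted p = 0.0846 with an estimated correlation). S100a8 was at 20.2 ± 1.39 CPM in WT and 9.58 ± 0.381 CPM in HO1-KO, and Siglecf at 8.84 ± 0.578 and 1.07 ± 0.290 CPM (SD, n = 3). In the dendritic cell list 12 of 16 members fell and 2 rose, with 13 lower and 2 higher when adjusted over the list alone (median -0.55, turning to 0.03 relative to the Y-linked genes, camera adjusted p = 0.00471, adjusted p = 0.228 with an estimated correlation). With the Y-linked scaling 4 members were lower and 2 higher. The list passed there as lower than the other genes (camera adjusted p = 0.000102), which this scaling shifts by the same amount as the list. The members that rose were Ccr9, from 94.4 ± 11.4 to 260 ± 27.4 CPM (SD, n = 3), and Ccr7. Of the sex-linked list, the 4 Y-linked genes fell and 1 member did not pass, also adjusted over the list alone (median -0.60, camera adjusted p = 0.0151, adjusted p = 0.228 with an estimated correlation).

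**Figure D3:**
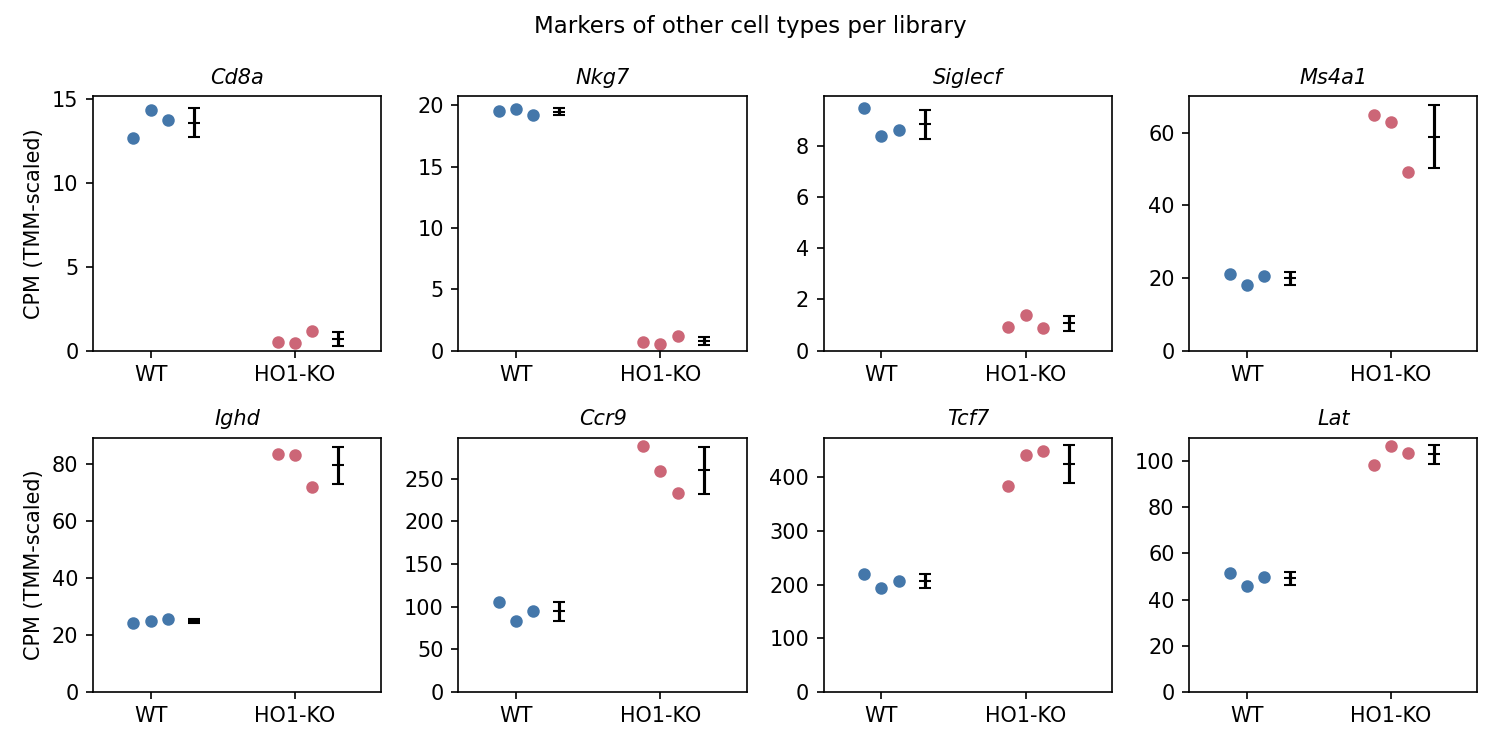
Level in CPM (vertical axes, starting at 0) of genes in the WT and HO1-KO libraries. Shown are Cd8a and Nkg7 (cytotoxic lymphocytes), Ms4a1 and Ighd (B cells), Siglecf (from the mast cell, eosinophil and basophil list), Ccr9, Tcf7 and Lat. Points are libraries and bars the mean and SD of 3 libraries, and Cd8a, Nkg7 and Siglecf average at most 1.07 CPM in HO1-KO, while the others are higher in every HO1-KO library.

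In the preset-correlation test 22 of 28 lists passed, 16 lower and 6 higher in HO1-KO, and none of the 28 passed with an estimated correlation (lowest adjusted p = 0.0846, with 7 lists at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, passed 23 lists. In another split of the 6 libraries, which mixes the genotypes unevenly and so keeps part of their difference, the preset-correlation test passed 19 lists. Fold changes are on the log2(CPM + 0.25) scale, which understates the change of low genes.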

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

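The settings relative to the Y-linked genes, with the deposited scaling alone and with other pseudocounts were chosen after the results were seen. Over the 7 other planned settings that refit the genes, 8149 to 9434 genes changed, and 7414 to 9036 changed when each library was left out. Hmox1 stayed between -0.95 and -0.93 and between -1.06 and -0.82 in these fits, past the threshold in each. Relative to the Y-linked genes it lay between -0.5073 and -0.1755 when each library was left out, and passed in 3 of 6. With the replicate numbers as a block, 8149 genes changed, 3969 higher and 4180 lower, and the Hmox1 value was -0.945. The values gave no sign that the numbers pair the libraries, which the labels leave open. The deviations of same-numbered libraries from their group means correlated at -0.173, 9.27e-05 and -0.227, and 0 of 6 libraries correlated best with their own number. The block ended the call of 1 of 169 named genes, Cxcl2, and of no list. The planned DESeq2 test was not run because the deposited values are not counts. Without 1 library, 21 to 23 lists passed; the immediate early list did not pass without WT replicate 2 (adjusted p = 0.056) or without HO1-KO replicate 1 (adjusted p = 0.0897). With an estimated correlation, 0 lists passed camera, 0 higher and 0 lower, with 7 at an unadjusted p under 0.05. Reads per library limit genes of low level, and 1 read is worth between 1.17 and 1.58 deposited units.

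With the deposited scaling alone, 5599 genes were higher and 3742 lower. Relative to the Y-linked genes, 12031 genes were higher and 745 lower. Of the 9000 genes called, 5867 were also called in this setting and 5193 of these in the same direction. List medians that turned positive there were those of heme and iron (0.0946), NRF2 targets (0.2885), inflammation (0.1905), hypoxia (0.4211), lipid efflux (0.0849), immediate early genes (0.3006), monocytes (0.2408), dendritic cells (0.0313), platelets (0.4797), fibroblasts (0.1373), endothelium (0.2363) and mitochondrial genes (0.4093). Of 169 named genes, 20 kept their direction there without passing and 18 changed direction. Those that turned positive were Cat (0.0371), Hbb-bt (0.068), Alas2 (0.2512), Itgb3 (0.0155), Cdh1 (0.2609), Krt5 (0.3628), Ddx3y (0.144), mt-Nd1 (0.3553), mt-Co1 (0.3418), mt-Nd3 (0.2854), mt-Co2 (0.202), Arg1 (0.2322), Vegfa (0.3133), Il10 (0.0658), Fth1 (0.118), Il1b (0.222), Isg15 (0.0109) and Sdhc (0.3348). This setting adds the same shift of 0.58 to every gene, which is why genes that fell by less turn sign. Without a filter the endothelial median was 0.0829; the cause was not tested. Leaving out a library gave -0.34 to 0.0865 for the platelet median and -0.71 to 0.1683 for Krt5, neither of which passed the threshold with all libraries.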

Other observations

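All tests of explanations in this part were chosen after the results were seen. In the monocyte list 11 of 20 members fell and 2 rose, with 12 lower and 2 higher when adjusted over the list alone (median -0.34, camera adjusted p = 8.94e-05, adjusted p = 0.213 with an estimated correlation). Mgst1 fell by 1.41 ± 0.08, while Vcan, which encodes the matrix proteoglycan versican, rose from 797 ± 40.7 to 1724 ± 140 CPM (SD, n = 3, 1.11 ± 0.07, log2, SE). In the immediate early list 15 of 24 fell and 3 rose, also adjusted over the list alone (median -0.28, camera adjusted p = 0.0199, adjusted p = 0.561 with an estimated correlation). It did not pass without WT replicate 2 (adjusted p = 0.056), without HO1-KO replicate 1 (adjusted p = 0.0897), with fry (adjusted p = 0.306) or relative to the Y-linked genes (adjusted p = 0.574). Klf4 fell by 0.77 ± 0.07, a call that ended relative to the Y-linked genes (-0.19 ± 0.11, SE, limma, adjusted p = 0.12), and the chaperone genes Hsph1 and Dnajb1 rose by 1.32 ± 0.07 and 0.84 ± 0.07. Hypoxia and glycolysis had 14 lower and 7 higher of 29 members and did not pass as a list (camera adjusted p = 0.132), except without HO1-KO replicate 3 (adjusted p = 0.0442) and without a filter (adjusted p = 0.0421). Oxidative phosphorylation had 9 higher and 1 lower of 32, or 8 and 1 adjusted over the list alone, and did not pass (adjusted p = 0.0837), except without HO1-KO replicate 1 (adjusted p = 0.0467), without a filter, with fry, with the deposited scaling alone and relative to the Y-linked genes. Mitochondrially encoded genes had 5 lower of 13, or 4 adjusted over the list alone, and did not pass (adjusted p = 0.0751), except without WT replicate 1 (adjusted p = 0.0382), without HO1-KO replicate 1 (adjusted p = 0.0237), without a filter and with fry. Platelet genes had 2 higher and 2 lower of 6 (adjusted p = 0.859), fibroblast genes 3 higher and 4 lower of 10 (adjusted p = 0.76) and endothelial genes 2 higher and 4 lower of 7 (adjusted p = 0.232, and 0.00194 with fry). Erythroid and epithelial genes had 3 and 4 tested members, too few for the test, with 1 lower, and with 1 higher and 1 lower. Relative to the Y-linked genes the medians turned positive in the monocyte (0.24), immediate early (0.30), hypoxia (0.42), mitochondrial (0.41), platelet (0.48), fibroblast (0.14) and endothelial (0.24) lists. In that setting the immediate early list had 15 higher and 0 lower members, hypoxia 20 and 0, mitochondrial genes 11 and 0 and monocytes 8 and 6. The monocyte, fibroblast and endothelial lists passed there as lower than the other genes, whose median was 0.59 (camera adjusted p = 0.000203, 0.0443 and 0.0269). Their distance from the other genes was the same as with the main scaling, since this setting shifts all genes alike. Fibroblast genes had 3 higher and 2 lower and endothelial genes 3 higher and 3 lower members. Among genes chosen after their values were seen, the nuclear receptor gene Pparg fell by 1.63 ± 0.13 and the lipid-binding protein gene Fabp4 fell by 1.48 ± 0.10.

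The fall of the macrophage list (median -0.71) was weighed against shares of RNA from other cells. A larger share of RNA from cells without Y-linked transcripts in the HO1-KO libraries would lower Y-linked and macrophage genes alike. The 4 Y-linked genes had a median of -0.606 and all fell, their X-linked homologs lay between 0.12 and 0.50 and none fell, and the macrophage list was at a median of -0.13 relative to them, so dilution is consistent with most of the fall of this list, and stays open beside an effect of the genotype. A lower share of macrophages with every other cell type raised alike is argued against by the NK list (-2.568) moving opposite to the B cell list (1.51). Whether the scaling lowers the list stays open, since the 4 scalings compared differed too little to decide it (medians -0.7115 to -0.6185). In the T cell list 12 of 20 genes rose, with Tcf7 the highest of those named at 425 CPM in HO1-KO. Of the genes that follow, Cd3e, Lck, Bcl11b, Cd4 and Icos were chosen after their values were seen. Rises of Lat, Tcf7, Ccr9, Cd3e, Lck and Bcl11b without Cd8a, Cd4 or Icos may come from T-lineage cells without a Y chromosome, such as tumour cells, whose lineage the labels do not give and which the macrophage sort would be meant to remove. Such added cells may also be behind the rises of the proliferation, cholesterol synthesis, ATF4 and ribosomal lists, which was not tested.

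Part of the pattern went beyond the fall of the Y-linked genes. Of 238 members of the 16 programme lists that fell, 56 also fell relative to the Y-linked genes and 29 rose. With a library left out, 41 to 71 fell in that setting. The count lay above a limit of 5% for dilution alone, which was set after the values were seen. A first count over 10 of these lists, picked after their values were seen, gave 56 lower and 15 higher of 204. All members share 1 reference of 4 genes with log2 fold changes from -0.66 to -0.43, so an error in it moves them together. The counts therefore cannot decide whether dilution alone accounts for the pattern. Falls larger than the differences among the Y-linked genes included Lpl (-1.62), Atp6v0d2 (-2.05), Gpnmb (-1.15) and Mmp12 (-1.01) relative to their mean. A biological change in the genes that fell further, or a change in the makeup of the sorted myeloid cells, may be behind this part. Neither was tested apart from the other.

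Hmox1 itself was weighed against the same dilution. Its log2 fold change relative to the Y-linked genes was -0.3677 with an upper 95% bound of -0.09. This rests on single libraries, since the bound lay above 0 without WT replicate 1 or 2 or without HO1-KO replicate 1 (0.0241, 0.0023 and 0.015), and HO1-KO replicate 3 lay above WT replicate 3. Whether dilution accounts for the whole fall therefore stays open. The residual 52.3% of the WT level may come from undeleted exons, incomplete deletion or other cells, which 1 value per gene does not separate.

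A further hypothesis was that DNA flanking the modified allele was carried along. Of 250 tested genes within 10 Mb of Hmox1, 15 (6%) changed more than 2-fold, against 7.14% of the genes elsewhere (odds ratio 0.83, 95% interval 0.456 to 1.4, Fisher's exact test, two-sided p = 0.619), which argues against a cluster of changes over 2-fold near the gene. Smaller changes were not counted, such as the rise of Mcm5 close to Hmox1 (0.71 ± 0.07, log2, SE).

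The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 9000 genes (limma) and the highest of the others 0, with up to 677 genes at an unadjusted p under 0.05 against 9938 in the real split. In all, 1 split, the real one, reached 9000. Every other split holds both genotypes within each group, which widens the spread there. A low gene count in these splits therefore followed from the design and does not bear on chance. For gene lists the real split gave 22, the highest of the others gave 19, and 1 split reached 22. The preset-correlation list test thus passed lists in a split in which the gene test called 0 genes. Such a split keeps part of the genotype difference between its groups, since the mix of genotypes is uneven. The 19 lists therefore do not show how often the test passes lists without any difference.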
